A study of Rattus norvegicus with 11 samples.

How the data were processed

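RNA was measured by sequencing of polyadenylated transcripts in 11 libraries of Sprague Dawley rat primary hippocampal neurons at day 7 in vitro. There were 4 libraries of neurons expressing WT H1.4, 4 of H1.4 CFT and 3 of GFP, which the labels call biological replicates. RNA was taken up in Trizol and purified on columns with a DNase step, per the labels. Per the submitters' processing notes, the authors aligned reads with STAR 2.7.2b to the mRatBN7.2 build and counted them per gene with HTSeq 0.10.0. The deposited values are raw counts per gene symbol, with no normalization. The annotation release and the strand setting of the counting are not given.

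Each file held 42177 entries, of which 42172 were genes and 5 were summary entries of the counter. Reads assigned to genes came to between 12070941 and 18846492 per library. Between 45.9% and 46.9% of reads were assigned to genes, and between 45.2% and 46.0% fell in no annotated feature. Of 29259 genes with at least 1 count, 17294 passed the low-count filter (filterByExpr by group, minimum count 10, minimum total 15) and were tested.

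Counts were analysed in R 4.3.3 with edgeR 4.0.16. All libraries were fitted together with TMM scaling, a term for group alone and the robust quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison. The adjusted threshold was 0.05, the biological coefficient of variation was 7.02% and 8 residual degrees of freedom were left. The comparisons were H1.4 CFT against WT H1.4, H1.4 CFT against GFP and WT H1.4 against GFP. In the report a gene or list passed, rose or fell only where the adjusted p was under the threshold. Whole-library measures were compared by exact two-sided permutation tests, adjusted over 45 tests.

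The comparisons, tests, gene lists, other settings and the rule for named genes were chosen before the data were examined. The 27 lists held 569 symbols, of which 4 (H1f3, Lrrtm1, Rigi and Auts2) had no match and 4 were matched through a synonym. The 26 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The linker histone list had 3 tested genes and no set test. With the estimated correlation, 2 lists passed for H1.4 CFT against WT H1.4 (immature neurons and astrocyte markers), 0 for H1.4 CFT against GFP, where fry gave 16, and 3 for WT H1.4 against GFP (inhibitory neurons, astrocyte markers and the endothelial, mural and fibroblast list). Named genes were H1f4, the 10 largest rises and 10 largest falls, and up to 4 members of each list past the threshold, by smallest p. The rises and falls were taken from genes past the threshold with a mean of at least 2 CPM, a symbol that is not a locus identifier and CPM values that did not overlap between the groups. A list that passed with no member past the threshold gave its 3 members with the smallest p. Some genes that meet these rules are not reported here.

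The fit was tested on simulated data with the depth and spread of these libraries. At true folds of 1.25, 1.5, 2 and 3 it recovered 48%, 76%, 90% and 100% of 50 genes each for H1.4 CFT against WT H1.4. The shares were 48%, 70%, 92% and 96% for H1.4 CFT against GFP, and 50%, 72%, 90% and 100% for WT H1.4 against GFP. False calls numbered 13 of 170, 11 of 164 and 13 of 169, and 0 of 50 unchanged lists were called in each. The simulation drew every gene and library independently, without number pairs or correlation between genes. The data have both, with an estimated correlation of 0.853 for glycolysis and hypoxia genes in H1.4 CFT against WT H1.4. These rates of false calls may therefore be too low for the real data.

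Whether equal replicate numbers mark shared cultures was checked by correlating residual values of equal numbers between groups. The correlations for numbers 1 to 4 were 0.149, 0.174, 0.192 and 0.142 between H1.4 CFT and WT H1.4. For numbers 2 to 4 they were 0.255, 0.124 and 0.163 between H1.4 CFT and GFP, and 0.206, 0.113 and 0.0927 between WT H1.4 and GFP. The best partner did not always have the equal number. CFT 1 went best with WT 2, CFT 4 with WT 3, CFT 3 and WT 3 with GFP 4, and WT 4 with GFP 3. The replicate number as a block had been set as an alternative before the data were examined. Genes whose span overlaps another gene were looked up in a table of the GRCr8 build, which is not the build of the files and served only for names and neighbours. It matched 29477 of the 42172 symbols, and 66 of the 183 named genes it held overlap another gene.

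The other settings tried were RLE scaling, DESeq2 1.42.0, no low-count filter, a stricter filter of 5 CPM in 3 libraries, the replicate block, a fit of only the groups compared, limma-voom, a non-robust spread, a fold threshold of 0.25 on the log2 scale, and the omission of each library. After the data were seen, alternatives were added for the number pairs, which are libraries 1 and 2 against 3 and 4. These were a block for the pair, counts summed within the pair, and tests within each pair. The tests within each pair take their spread from libraries of the same group and pair. Their p-values and counts of genes and lists cover no variation beyond that. No library was left out of the main values.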

Results

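Polyadenylated RNA was sequenced in 11 libraries of rat primary hippocampal neurons at day 7 in vitro. The neurons expressed wild-type linker histone H1.4 (WT H1.4, n = 4), H1.4 with a C-terminal frameshift tail (H1.4 CFT, n = 4) or green fluorescent protein as the control (GFP, n = 3). Linker histones bind the DNA that enters and leaves the nucleosome and help to compact chromatin. The libraries are called here by group and replicate number, with numbers 1 to 4 for WT H1.4 and H1.4 CFT and 2 to 4 for GFP. Reads assigned to genes came to between 12070941 (GFP 3) and 18846492 (WT 1) per library. In exact two-sided permutation tests of these totals p was 0.914 for H1.4 CFT against WT H1.4, 0.0571 for H1.4 CFT against GFP and 0.143 for WT H1.4 against GFP. Expression is given as CPM (counts scaled to library size) with TMM scaling, as mean ± SD over n = 4, 4 and 3 libraries.

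The 3 linker histone genes with enough reads to test, H1f2, H1f0 and H1f10, were lowest in H1.4 CFT neurons. These are levels of polyadenylated transcripts only. H1f2, a replication-dependent linker histone, fell 2.09-fold in H1.4 CFT against WT H1.4 (21.7 ± 1.90 against 45.2 ± 5.44 CPM, log2 fold change -1.06, SE 0.090, adjusted p = 3.35e-07) and 2.89-fold against GFP, where it stood at 62.8 ± 6.39 CPM (log2 fold change -1.53, SE 0.095, adjusted p = 2.40e-08). H1f0, the linker histone of differentiated cells, fell 1.52-fold against WT H1.4 (53.9 ± 0.474 against 81.9 ± 3.66 CPM, adjusted p = 5.95e-08) and 1.79-fold against GFP (log2 fold change -0.84, SE 0.051, adjusted p = 2.26e-09). For H1f10 the log2 fold changes were -0.33 (SE 0.058, adjusted p = 0.000192) and -0.27 (SE 0.063, adjusted p = 0.00332). WT H1.4 neurons also had less H1f2 and H1f0 than GFP neurons, with log2 fold changes of -0.47 (SE 0.092, adjusted p = 0.0171) and -0.24 (SE 0.050, adjusted p = 0.0232). Those last calls did not hold without single libraries. The adjusted p for H1f2 became 0.132 without GFP 3, 0.168 without GFP 4 and 0.0611 without WT 2, and that for H1f0 became 0.164 without GFP 3, 0.19 without GFP 4, 0.0924 without WT 2, 0.0509 without WT 3 and 0.0502 without WT 4.

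H1f4, the rat gene for H1.4, gave very few reads in any of these libraries of polyadenylated RNA. It had 4, 3, 1 and 5 counts in WT 1 to 4, 6, 8, 5 and 6 counts in CFT 1 to 4, and 2, 0 and 2 counts in GFP 2 to 4. Summed by group this was 0.189 CPM, here without TMM scaling, in WT H1.4 (95% exact Poisson interval 0.101 to 0.324), 0.358 in H1.4 CFT (0.232 to 0.529) and 0.0930 in GFP (0.0254 to 0.238). Such intervals cover counting error only. The 0 counts in GFP 3 allow up to 0.249 CPM, from a limit of 3 counts. The gene lay below the low-count filter. Without that filter the log2 fold changes were 0.79 (SE 0.69, adjusted p = 0.479) for H1.4 CFT against WT H1.4, 1.80 (SE 0.89, adjusted p = 0.163) for H1.4 CFT against GFP and 1.01 (SE 0.95, adjusted p = 0.775) for WT H1.4 against GFP. An exact two-sided permutation test of the CPM gave p = 0.0286 for H1.4 CFT against GFP, the smallest it can give, with a Benjamini-Hochberg adjusted p of 0.0714 over 45 library tests. Neither the species nor the sequence of the constructs is given in the labels, so reads of a construct need not fall on the rat gene and this count does not check the labels.

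**Figure D1:**
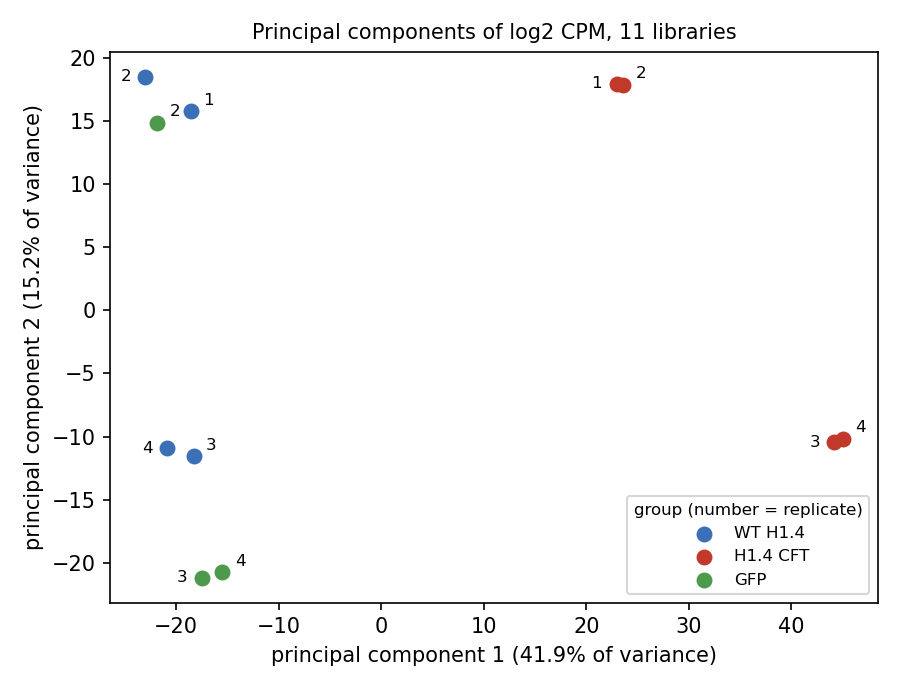
Scores of the 11 libraries on the first 2 principal components of log2 CPM of the tested genes, with 1 point per library, coloured by group and marked with its replicate number. The first component (41.9% of the variance) sets the H1.4 CFT libraries apart at scores of 22.9 and above, and the second (15.2%) sets numbers 1 and 2 apart from numbers 3 and 4 in every group, where GFP has no number 1.

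Across whole libraries, H1.4 CFT neurons had more detected genes and a larger share of mitochondrial transcripts. With all libraries thinned to 12070941 counts, 22798 ± 94.4 genes were detected in H1.4 CFT, 21728 ± 157 in WT H1.4 and 21996 ± 63.3 in GFP. Mitochondrially encoded genes took 3.26 ± 0.115% of gene counts in H1.4 CFT, 2.81 ± 0.138% in WT H1.4 and 2.91 ± 0.0905% in GFP. In both measures every H1.4 CFT library lay above every library of the other groups (exact two-sided permutation p = 0.0286 for each comparison, the smallest possible, adjusted p = 0.0714 over 45 tests). The share of reads that were not aligned was lower in WT H1.4 (0.895 ± 0.0476%) than in H1.4 CFT (1.51 ± 0.146%) and GFP (1.65 ± 0.247%), with the same exact p and adjusted p. Within WT H1.4 and H1.4 CFT the libraries numbered 1 and 2 resembled each other, and within every group so did 3 and 4. The ratio of observed to counting variance was 1.79 to 2.26 between libraries of a group within these number pairs and 3.79 to 9.27 across them. No label names a batch, so the main counts are also given within each number pair.

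H1.4 CFT neurons had lower levels of transcripts of neuronal structure, synapses, ion channels, cholesterol synthesis and glycolysis than WT H1.4 neurons. By the list test 16 of 26 lists passed, and with an estimated inter-gene correlation only the immature neuron and astrocyte lists did. Dpysl3, Dcx, Stmn1 and Stmn2, cytoskeletal genes of growing neurons, had log2 fold changes of -0.57, -0.56, -0.49 and -0.51 (adjusted p of 6.82e-08, 6.82e-08, 9.47e-08 and 4.37e-07). Astrocyte markers, interferon-response genes, core histone genes and mitochondrially encoded genes were higher, with Gfap, the intermediate filament of astrocytes, 1.83-fold higher (557 ± 51.5 against 305 ± 16.6 CPM, adjusted p = 2.08e-07). Of 17294 genes tested, 6217 passed an adjusted p of 0.05, 2893 higher and 3324 lower, and 472 rose and 212 fell at least 2-fold. This comparison sets the mutant against the wild-type protein, both expressed from outside.

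The largest changes named are among called genes with a symbol that is not a locus identifier, a mean of at least 2 CPM and CPM values that did not overlap between the groups, here and in the comparisons below. Of these, Snai3, a Snail-family transcriptional repressor, rose most (6.81 ± 2.00 against 0.448 ± 0.0483 CPM, log2 fold change 3.90, SE 0.27, adjusted p = 9.00e-09). Lhx3, a LIM-homeodomain transcription factor of pituitary and motor neuron development, rose 7.94-fold (5.39 ± 1.68 against 0.669 ± 0.186 CPM). Misp, an actin-binding protein of the mitotic spindle, rose 7.48-fold and Cfap44, a protein of cilia and flagella, rose 6.63-fold. Baiap3, which acts in dense-core vesicle release, rose 5.14-fold (13.0 ± 1.90 against 2.53 ± 0.271 CPM). Further large rises were in Mogat2 (5.06-fold), Tmem176b (5.05-fold), the acrosin gene Acr (3.86-fold) and Ccdc9b (3.70-fold). Adjusted p for these genes ran from 2.78e-09 for Baiap3 to 0.000507 for Misp. Nrgn, the postsynaptic calmodulin-binding protein neurogranin, fell most within the same limits, 3.90-fold (15.3 ± 8.74 against 59.6 ± 8.29 CPM, log2 fold change -1.96, SE 0.37, adjusted p = 0.00378). Htr2a, the serotonin 2A receptor, fell 3.67-fold (1.46 ± 0.627 against 5.36 ± 0.840 CPM, adjusted p = 4.42e-06). A pair of neuronal membrane genes also fell, Npbwr1, a neuropeptide B and W receptor, 3.47-fold, and Kcnj12, an inward-rectifier potassium channel, 3.28-fold. The other largest falls within these limits were in Slc27a2 (3.80-fold), Sidt1 (3.61-fold), Usp43 (3.61-fold), Cyp2s1 (3.60-fold), Mrap2 (3.31-fold) and the sodium-proton exchanger gene Slc9a2 (3.26-fold), with adjusted p of at most 0.00781 among all 10.

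**Figure D2:**
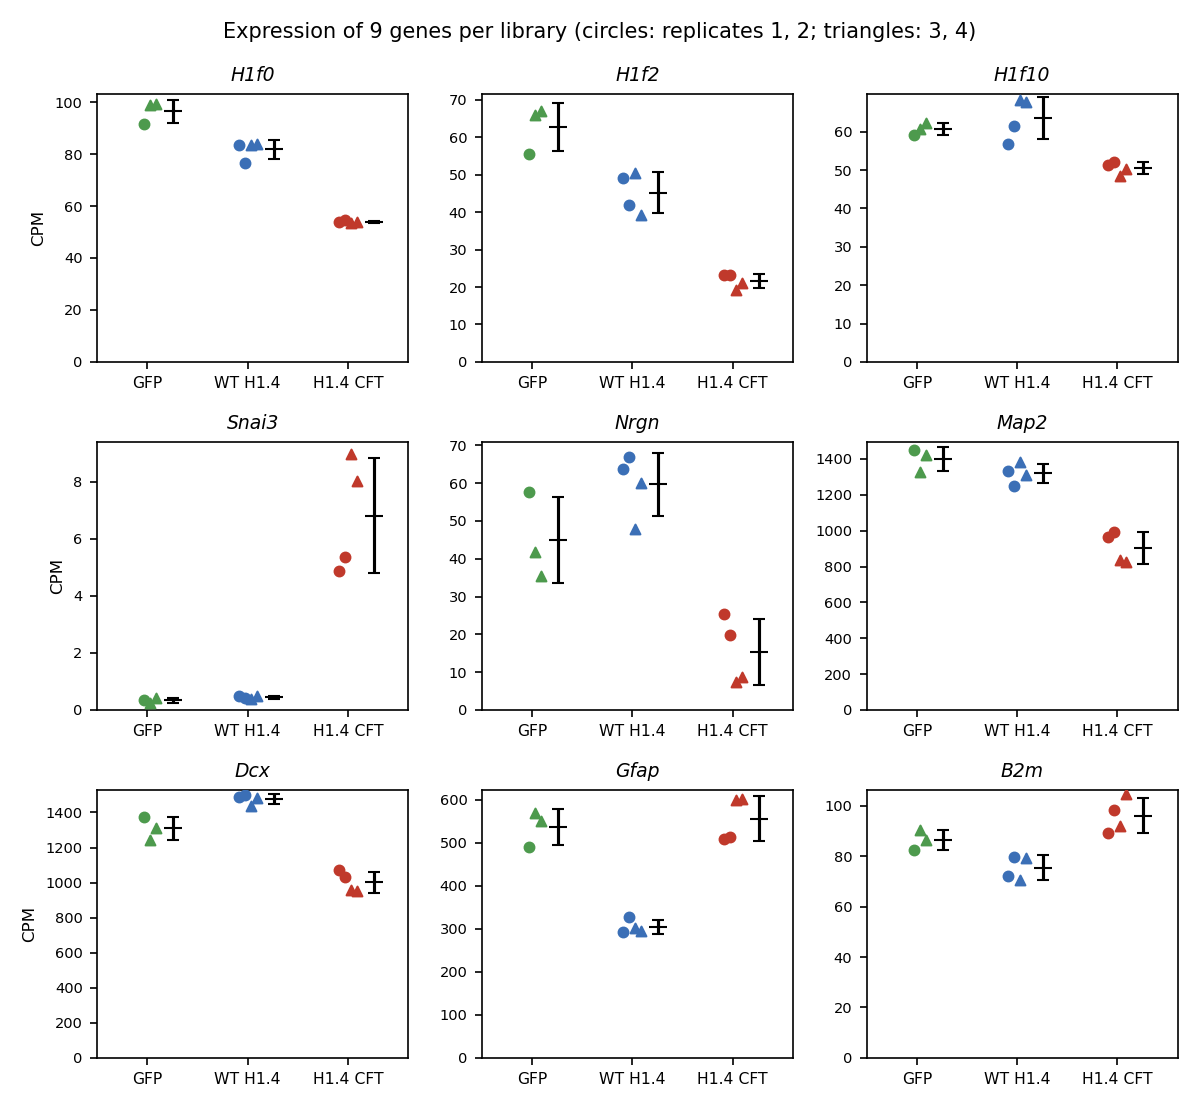
CPM of 9 selected genes on linear axes from 0, for GFP, WT H1.4 and H1.4 CFT, with 1 point per library (circles for replicates 1 and 2, triangles for 3 and 4) and bars of mean ± SD. Snai3 averaged 6.81 CPM in H1.4 CFT and 0.448 CPM in WT H1.4, and H1f2 averaged 21.7 CPM in H1.4 CFT against 45.2 CPM in WT H1.4 and 62.8 CPM in GFP.

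Genes of the synapse fell together. Among excitatory postsynaptic genes, 20 of 29 measured members fell, 1 rose and 8 did not pass (adjusted over the list alone, 1 rose and 23 fell), with median log2 fold change -0.24, camera adjusted p = 3.11e-08, adjusted p = 0.31 with an estimated correlation. Lrrtm2, a synaptic adhesion protein, fell 2.00-fold (22.2 ± 2.84 against 44.5 ± 3.04 CPM), and Cacng2, the AMPA receptor partner stargazin, fell 1.58-fold. In the presynaptic and vesicle list, 21 of 30 measured members fell, 2 rose and 7 did not pass (adjusted over the list alone, 2 rose and 22 fell), with median log2 fold change -0.28, camera adjusted p = 4.02e-08, adjusted p = 0.31 with an estimated correlation. The active-zone genes Erc2, Unc13a and Pclo fell 1.46-fold, 1.38-fold and 1.49-fold, and the vesicle protein gene Syp fell 1.27-fold. Of the voltage-gated ion channels, 20 of 31 measured members fell and 11 did not pass (adjusted over the list alone, 24 fell) (median log2 fold change -0.30, camera adjusted p = 6.32e-08, adjusted p = 0.31 with an estimated correlation). Kcna2 fell 1.34-fold and the sodium channel subunit gene Scn3b fell 1.47-fold (log2 fold changes of -0.42 and -0.56, SE 0.055 and 0.072). Of the neuropeptide and secreted factor genes, 10 of 18 measured members fell, 3 rose and 5 did not pass (adjusted over the list alone, 3 rose and 11 fell) (median log2 fold change -0.31, camera adjusted p = 0.000634, adjusted p = 0.198 with an estimated correlation). Among them Chgb, a granin of secretory vesicles, fell 1.55-fold and Tac1, the substance P precursor, fell 2.84-fold. The inhibitory neuron list did not pass as a set (camera adjusted p = 0.617, median log2 fold change 0.0035), although 8 of 25 measured members rose, 8 fell and 9 did not pass (adjusted over the list alone, 11 rose and 8 fell). Its GABA receptor subunit gene Gabra5 had a log2 fold change of -0.64.

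Markers of immature neurons and of mature neurons were both lower. Among genes of immature and migrating neurons, 12 of 18 measured members fell, 2 rose and 4 did not pass (adjusted over the list alone, 4 rose and 12 fell) (median log2 fold change -0.40, camera adjusted p = 1.16e-07, adjusted p = 0.023 with an estimated correlation). Of the neurofilament and mature neuron genes, 11 of 16 measured members fell, 1 rose and 4 did not pass (adjusted over the list alone, 1 rose and 11 fell) (median log2 fold change -0.42, camera adjusted p = 1.39e-07, adjusted p = 0.31 with an estimated correlation). Map2, the dendritic microtubule-associated protein, fell 1.46-fold (905 ± 87.9 against 1319 ± 55.3 CPM), and Mapt, which encodes tau, fell 1.39-fold. In the axon guidance and adhesion list, 18 of 38 measured members fell, 2 rose and 18 did not pass (adjusted over the list alone, 3 rose and 18 fell) (median log2 fold change -0.16, camera adjusted p = 0.000336, adjusted p = 0.31 with an estimated correlation). Its members moved both ways, as the semaphorin receptor gene Nrp1 fell 1.39-fold while Efnb2 and Sema5a rose 1.45-fold and 1.46-fold. Immediate early and activity-regulated genes did not pass as a set (camera adjusted p = 0.527), and 6 of 30 measured members fell, 4 rose and 20 did not pass (adjusted over the list alone, 4 rose and 6 fell). Egr3 and Dusp6 fell 1.91-fold and 1.73-fold, and Jun rose 1.39-fold.

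Lipid and sugar metabolism genes were lower in H1.4 CFT than in WT H1.4. Of the cholesterol synthesis genes, 14 of 21 measured members fell and 7 did not pass (adjusted over the list alone, 18 fell) (median log2 fold change -0.53, camera adjusted p = 3.11e-08, adjusted p = 0.33 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, fell 1.59-fold (221 ± 40.5 against 352 ± 4.44 CPM), and Nsdhl and Idi1 fell 1.45-fold and 1.57-fold. Of the glycolysis and hypoxia genes, 10 of 23 measured members fell and 13 did not pass (adjusted over the list alone, 12 fell) (median log2 fold change -0.46, camera adjusted p = 1.82e-06, adjusted p = 0.439 with an estimated correlation). The enzyme genes Eno1, Gapdh and Pgk1 fell 1.46-fold, 1.37-fold and 1.82-fold. Mitochondrially encoded genes went the other way, where 7 of 15 measured members rose, 1 fell and 7 did not pass (adjusted over the list alone, 8 rose and 1 fell) (median log2 fold change 0.14, camera adjusted p = 0.0125, adjusted p = 0.445 with an estimated correlation), with ND2 1.28-fold and ND1 1.17-fold higher. Nuclear genes of oxidative phosphorylation did not pass as a set (camera adjusted p = 0.0746, but 0.0472 without WT 2), and 8 of 35 measured members rose, 1 fell and 26 did not pass (adjusted over the list alone, 7 rose). Cytosolic ribosomal protein genes hardly moved, and 11 of 83 measured members fell, 2 rose and 70 did not pass (adjusted over the list alone, 2 rose and 7 fell) (median log2 fold change -0.031, camera adjusted p = 0.373).

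Transcripts of glia and of other cell types were partly higher beside this fall of neuronal genes. Part of this went with low values in WT H1.4. The astrocyte and the endothelial, mural and fibroblast lists were lower in WT H1.4 than in GFP (medians -0.24 and -0.14). Neither list passed in H1.4 CFT against GFP (camera adjusted p of 0.326 and 0.713). Against WT H1.4, 10 of 17 measured astrocyte markers rose and 7 did not pass (adjusted over the list alone, 11 rose) (median log2 fold change 0.23, camera adjusted p = 1.34e-08, adjusted p = 0.00398 with an estimated correlation). Gja1, the gap junction protein of astrocytes, rose 1.52-fold (127 ± 3.15 against 83.5 ± 3.39 CPM), and Mlc1 rose 1.56-fold. For endothelial, mural and fibroblast markers, 9 of 19 measured members rose, 3 fell and 7 did not pass (adjusted over the list alone, 10 rose and 3 fell) (median log2 fold change 0.25, camera adjusted p = 0.0401, adjusted p = 0.31 with an estimated correlation), and the adjusted p became 0.0632 without CFT 2, 0.0638 without WT 3 and 0.0704 without WT 4. The endothelial receptor gene Tek rose 3.26-fold (3.52 ± 0.740 against 1.07 ± 0.190 CPM) and the collagen gene Col1a2 rose 1.99-fold (12.9 ± 1.05 against 6.43 ± 1.43 CPM). For ependymal and choroid plexus markers, 4 of 11 measured members rose and 7 did not pass (adjusted over the list alone, 4 rose) (median log2 fold change 0.45, camera adjusted p = 0.0231, adjusted p = 0.439 with an estimated correlation), and the adjusted p became 0.0739 without CFT 3 and 0.0543 without WT 1. Foxj1, the transcription factor of motile cilia, rose 1.78-fold. Oligodendrocyte lineage markers did not pass (camera adjusted p = 0.923), and 0 of 13 measured members passed (adjusted over the list alone, 0 passed). Of the microglia and macrophage markers, 1 of 5 measured members rose, 1 fell and 3 did not pass (adjusted over the list alone, 1 rose and 1 fell), with a camera adjusted p of 0.548. Csf1r rose from 0.433 to 1.13 CPM while P2ry12 fell 1.51-fold. The cell cycle list passed (median log2 fold change 0.19, camera adjusted p = 0.00392, adjusted p = 0.59 with an estimated correlation), and 4 of 26 measured members rose and 22 did not pass (adjusted over the list alone, 4 rose), led by the replication helicase genes Mcm7 (1.37-fold) and Mcm4 (1.17-fold).

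Interferon-response genes rose with the largest median of the 26 lists tested. Here 14 of 20 measured members rose, 1 fell and 5 did not pass (adjusted over the list alone, 15 rose and 1 fell) (median log2 fold change 0.72, camera adjusted p = 7.07e-06, adjusted p = 0.31 with an estimated correlation). The guanylate-binding protein gene Gbp2 rose 2.65-fold (8.29 ± 2.41 against 3.16 ± 0.593 CPM), and B2m, the class I light chain, rose 1.28-fold. Of the core histone genes, 7 of 19 measured members rose, 1 fell and 11 did not pass (adjusted over the list alone, 7 rose and 1 fell) (median log2 fold change 0.24, camera adjusted p = 0.0082, adjusted p = 0.31 with an estimated correlation). Hist3h2a and Hist1h2bq rose 1.68-fold and 1.76-fold, though genes of this kind have near-identical copies. Only polyadenylated RNA was sequenced, so any histone transcripts without a poly(A) tail are left out of these values. Chromatin regulators of neurodevelopmental disorders did not pass as a set (camera adjusted p = 0.891, median log2 fold change 0.011), and 8 of 39 measured members rose, 5 fell and 26 did not pass (adjusted over the list alone, 8 rose and 4 fell). Chd3, a nucleosome remodeller, fell 1.42-fold (519 ± 24.1 against 734 ± 21.2 CPM), and Chd2 and Ehmt1 rose 1.17-fold and 1.12-fold. For p53 targets, 7 of 20 measured members rose, 3 fell and 10 did not pass (adjusted over the list alone, 8 rose and 3 fell) (camera adjusted p = 0.0805, but 0.0171 without CFT 2), with the nuclease gene Aen 1.72-fold higher and Plk2 1.39-fold lower. In the unfolded protein and integrated stress list, 8 of 24 measured members fell, 3 rose and 13 did not pass (adjusted over the list alone, 3 rose and 8 fell) (camera adjusted p = 0.148, but 0.0458 without WT 3), and Atf4 and Chac1 fell 1.37-fold and 2.14-fold. Of the heat shock genes, 4 of 13 measured members fell, 2 rose and 7 did not pass (adjusted over the list alone, 2 rose and 4 fell) (camera adjusted p = 0.548). That list's median and test pointed down and its mean log2 fold change was 0.055, with log2 fold changes of -0.49 for Hsph1 and 1.14 for Hspb1.

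The direction of change went with abundance. Among genes under 1 CPM, 267 rose and 42 fell, with a median log2 fold change of 0.34 over 1677 genes. Among genes over 100 CPM, 272 rose and 1017 fell, with a median of -0.08 over 2498 genes. The 2 groups did not overlap in 5990 genes (34.6%, where chance gives 2.86%). Within numbers 1 and 2 alone 4623 genes passed, and within numbers 3 and 4 alone 7561 passed. All 16 called lists passed within numbers 3 and 4 and 12 within numbers 1 and 2, where the endothelial, ependymal, cell cycle and core histone lists did not. With number pairs summed 2723 genes passed, 23 of the 121 named genes called lost their call and the endothelial list did not pass (adjusted p = 0.0583). Of the genes named above these were Nrgn (adjusted p = 0.148), Mrap2 (0.128), Idi1 (0.0871), Pgk1 (0.17), ND1 (0.0692), Csf1r (0.0745), Mcm4 (0.099) and Ehmt1 (0.119). The spans of Acr, Baiap3, Cfap44, Chd3, Cyp2s1, Dpysl3, Erc2, Fdps, H1f2, Hist1h2bq, Idi1, Lrrtm2, Mapt, Mcm7, Misp, Mlc1, Mogat2, Nrp1, P2ry12, Sema5a, Slc9a2, Stmn1 and Tmem176b overlap another gene in the GRCr8 table, and the strand setting of the counting is not given, so their values are uncertain.

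**Figure D3:**
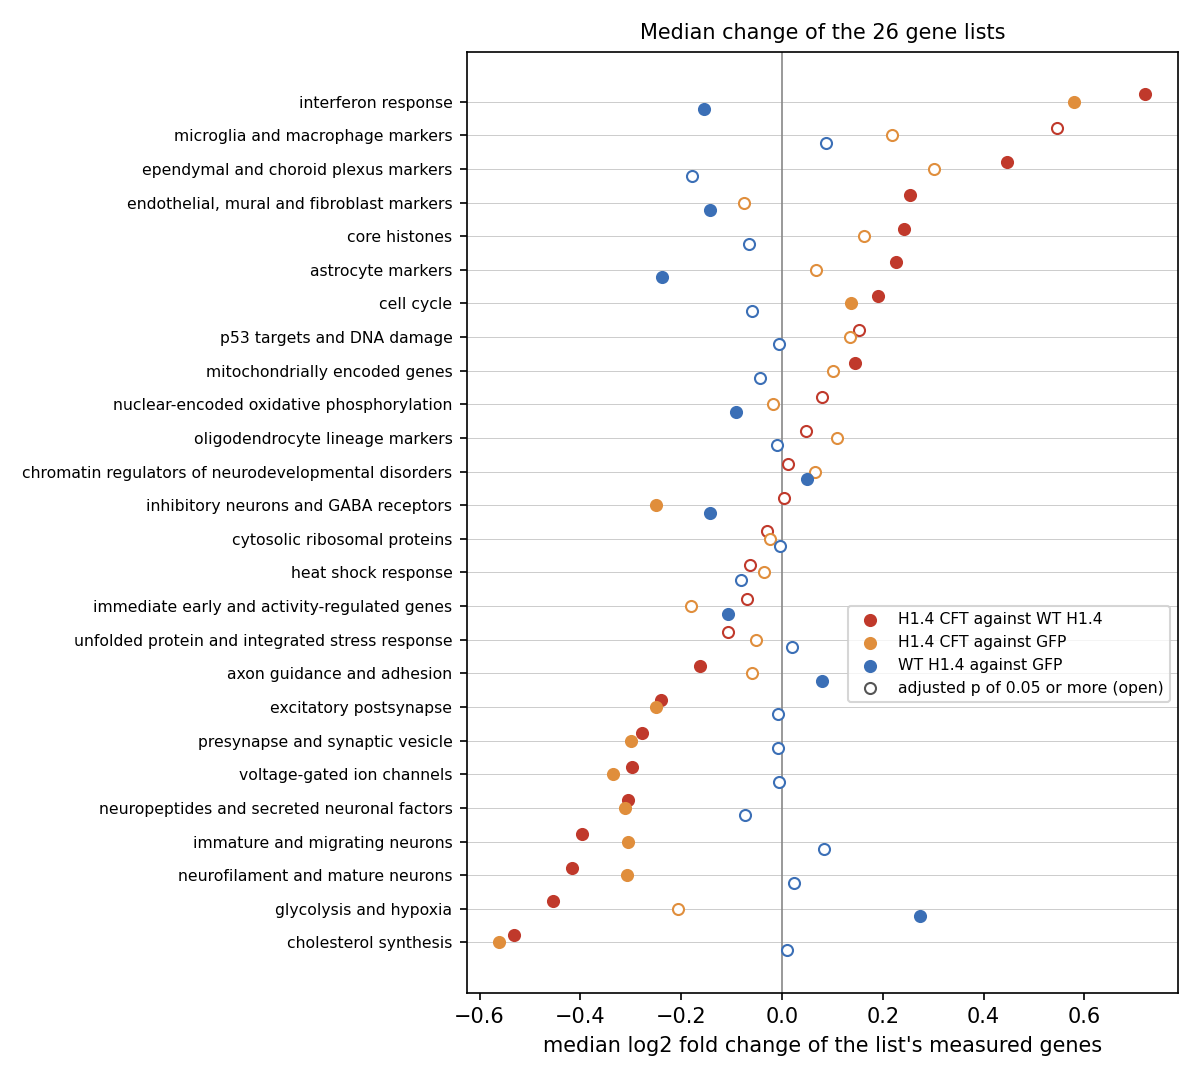
Median log2 fold change of each of the 26 tested lists in the 3 comparisons, with filled points where camera gave an adjusted p under 0.05 and open points elsewhere. Interferon-response genes had a median of 0.72 in H1.4 CFT against WT H1.4, and cholesterol synthesis genes had a median of -0.53.

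**Figure D4:**
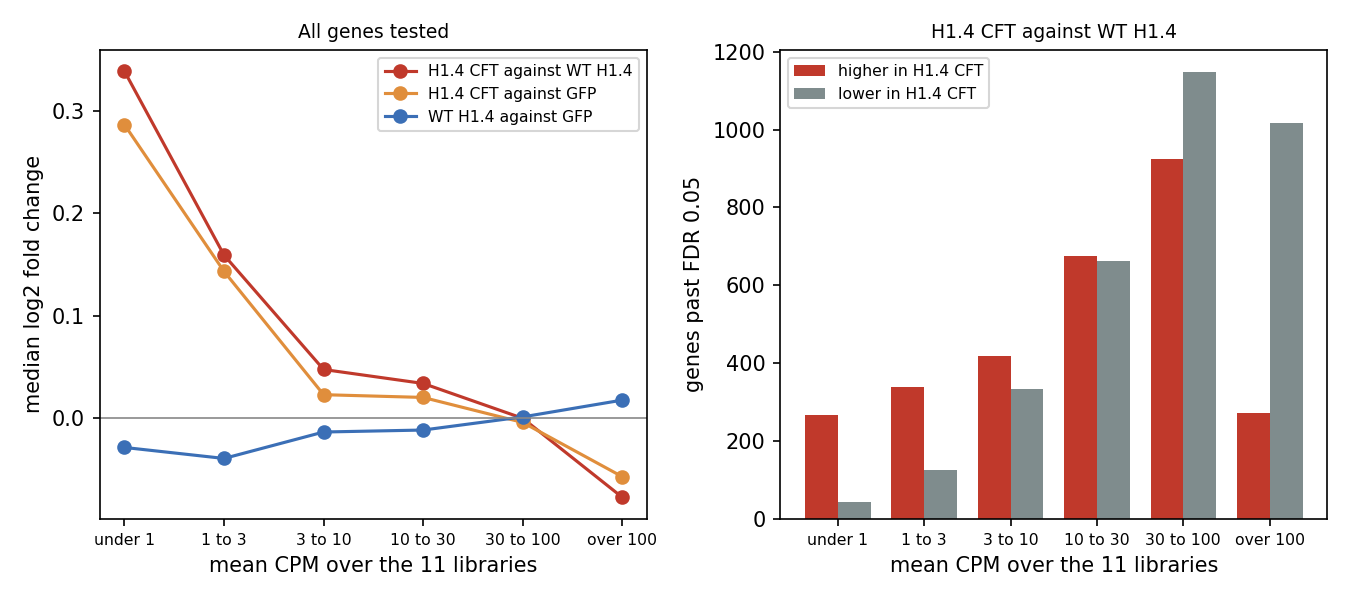
Median log2 fold change of the tested genes in 6 classes of mean CPM for the 3 comparisons (left), and the numbers of genes that passed as higher or lower in H1.4 CFT against WT H1.4 in each class (right). The median fell from 0.34 in genes under 1 CPM to -0.08 in genes over 100 CPM for H1.4 CFT against WT H1.4, and stayed between -0.04 and 0.02 for WT H1.4 against GFP.

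Against the GFP control, H1.4 CFT neurons again had lower synaptic, channel, neuropeptide and neurofilament transcripts, and higher interferon-response transcripts. By the list test 10 of 26 lists passed, and with an estimated inter-gene correlation 0 did. Nefl and Nefm, the light and medium neurofilament genes, fell 2.04-fold (51.3 ± 10.3 against 105 ± 5.59 CPM) and 2.16-fold (77.3 ± 15.2 against 166 ± 14.6 CPM), with adjusted p of 0.000292 and 0.000386. Egr3, an activity-regulated transcription factor, fell 2.78-fold (5.39 ± 0.676 against 14.9 ± 1.76 CPM, log2 fold change -1.48, SE 0.13, adjusted p = 1.53e-07). Astrocyte markers as a list did not pass here (camera adjusted p = 0.326). In all, 5098 genes passed, 2302 higher and 2796 lower, of which 399 rose and 246 fell at least 2-fold. The question here is what the mutant protein does to neurons that express no added histone.

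Snai3 rose 18.9-fold against GFP (6.81 ± 2.00 against 0.345 ± 0.0859 CPM, log2 fold change 4.24, SE 0.32, adjusted p = 3.77e-08). Cfap44, Misp and Lhx3 rose 7.46-fold, 7.41-fold and 4.99-fold. Eqtn and Catsperg, genes of the sperm acrosome and of the sperm calcium channel, rose 4.64-fold (15.5 ± 3.62 against 3.36 ± 0.519 CPM) and 3.75-fold (10.2 ± 0.653 against 2.72 ± 0.740 CPM). Further large rises were in Baiap3 (4.46-fold), Mogat2 (4.16-fold) and the thromboxane receptor gene Tbxa2r (3.79-fold), and adjusted p for these genes was at most 0.00161. Within the limits of 2 CPM and no overlap, Usp43, which encodes a deubiquitinase, fell most, 4.73-fold (0.814 ± 0.503 against 3.83 ± 0.489 CPM, log2 fold change -2.24, SE 0.33, adjusted p = 5.55e-05). St18, a zinc finger transcription factor, fell 3.28-fold (18.5 ± 7.79 against 60.7 ± 6.29 CPM), and Cpne7, a calcium-dependent membrane-binding copine, fell 3.30-fold (11.3 ± 3.50 against 37.1 ± 3.32 CPM). The remaining large falls were in Sidt1 (4.17-fold), Mrap2 (3.74-fold), Coch (3.68-fold), Slc9a2 (3.60-fold), Htr2a (3.54-fold), Slc27a2 (3.28-fold) and Cfap57 (3.24-fold), with adjusted p of at most 0.00807 among the 10 falls.

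Neuronal lists made up 7 of the 8 lists that passed as lower. For presynaptic genes, 22 of 30 measured members fell, 2 rose and 6 did not pass (adjusted over the list alone, 2 rose and 22 fell) (median log2 fold change -0.30, camera adjusted p = 5.15e-10, adjusted p = 0.433 with an estimated correlation), and Syp fell 1.44-fold (365 ± 31.5 against 524 ± 21.7 CPM). For excitatory postsynaptic genes, 15 of 29 measured members fell and 14 did not pass (adjusted over the list alone, 18 fell) (median log2 fold change -0.25, camera adjusted p = 3.20e-07, adjusted p = 0.433 with an estimated correlation), with Lrrtm2 falling 2.29-fold and the AMPA receptor gene Gria1 1.28-fold. For voltage-gated channels, 20 of 31 measured members fell, 1 rose and 10 did not pass (adjusted over the list alone, 1 rose and 24 fell) (median log2 fold change -0.34, camera adjusted p = 6.89e-08, adjusted p = 0.433 with an estimated correlation), with Kcna2 falling 1.39-fold. Among mature neuron genes, 11 of 16 measured members fell, 1 rose and 4 did not pass (adjusted over the list alone, 1 rose and 12 fell) (median log2 fold change -0.31, camera adjusted p = 6.98e-08, adjusted p = 0.365 with an estimated correlation), and Map2 fell 1.55-fold. In the immature neuron list, 11 of 18 measured members fell, 3 rose and 4 did not pass (adjusted over the list alone, 4 rose and 11 fell) (median log2 fold change -0.30, camera adjusted p = 1.96e-05, adjusted p = 0.0996 with an estimated correlation), and Neurod6 fell 1.46-fold. Among neuropeptide genes, 10 of 18 measured members fell, 1 rose and 7 did not pass (adjusted over the list alone, 1 rose and 11 fell) (median log2 fold change -0.31, camera adjusted p = 2.34e-05, adjusted p = 0.0996 with an estimated correlation), with Vgf, a secreted neuronal protein, falling 1.72-fold. The inhibitory neuron list passed as lower, 9 of 25 measured members fell, 2 rose and 14 did not pass (adjusted over the list alone, 2 rose and 10 fell) (median log2 fold change -0.25, camera adjusted p = 0.00207, adjusted p = 0.204 with an estimated correlation), and Gphn, the scaffold of inhibitory synapses, had a log2 fold change of -0.32. Cholesterol synthesis was the eighth list, 11 of 21 measured members fell and 10 did not pass (adjusted over the list alone, 14 fell) (median log2 fold change -0.56, camera adjusted p = 4.80e-08, adjusted p = 0.443 with an estimated correlation), and Nsdhl and Cyp51 fell 1.64-fold and 1.54-fold.

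As lists, interferon-response and cell cycle genes passed as higher. In the first, 9 of 20 measured members rose, 1 fell and 10 did not pass (adjusted over the list alone, 11 rose and 1 fell) (median log2 fold change 0.58, camera adjusted p = 0.00148, adjusted p = 0.433 with an estimated correlation), and Gbp2 and Mx1 rose 2.09-fold and 1.67-fold. In the second, 2 of 26 measured members rose and 24 did not pass (adjusted over the list alone, 2 rose) (median log2 fold change 0.14, camera adjusted p = 0.0447, adjusted p = 0.709 with an estimated correlation), with Mcm4 1.31-fold higher, and the camera adjusted p became 0.213 without GFP 2, 0.185 without CFT 3 and 0.116 without CFT 4. With the replicate number as a block, 4 more lists passed. They were the glycolysis and hypoxia list (adjusted p = 0.00623 against 0.0845 without the block), core histones (0.0302 against 0.0525), ependymal markers (0.0415 against 0.0812) and p53 targets (0.0432 against 0.056). With a block for the number pair, or with number pairs summed, the glycolysis, core histone and p53 lists passed as well, but the ependymal list did not (adjusted p = 0.0525 and 0.0593). In the fit without a block, an estimated correlation gave adjusted p of 0.733, 0.448, 0.538 and 0.448 for the glycolysis, core histone, ependymal and p53 lists. Of the glycolysis and hypoxia genes, 1 of 23 measured members fell and 22 did not pass (adjusted over the list alone, 0 passed). Of the core histone genes, 6 of 19 measured members rose, 1 fell and 12 did not pass (adjusted over the list alone, 6 rose and 1 fell), with Hist1h2bq 1.62-fold higher. Of the ependymal markers, 3 of 11 measured members rose and 8 did not pass (adjusted over the list alone, 3 rose), with Ccdc153 2.04-fold higher. Leaving out single libraries also let these 4 pass, at 0.00126 without GFP 4, 0.00856 without CFT 1 and 0.0102 without CFT 2 for glycolysis and hypoxia, 0.0319 without GFP 3, 0.0357 without GFP 4, 0.0244 without CFT 1, 0.0215 without CFT 2, 0.0458 without WT 1, 0.0446 without WT 2 and 0.0404 without WT 3 for core histones, 0.0441 without GFP 4, 0.0479 without CFT 1 and 0.0452 without CFT 2 for ependymal markers and 0.0407 without GFP 3, 0.0354 without CFT 1 and 0.0112 without CFT 2 for p53 targets. Of the p53 targets, 8 of 20 measured members rose, 1 fell and 11 did not pass (adjusted over the list alone, 9 rose and 1 fell), with Bbc3, the cell death gene PUMA, 1.57-fold higher.

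Markers of other cell types moved apart in this comparison. Among astrocyte markers, 4 of 17 measured members rose, 1 fell and 12 did not pass (adjusted over the list alone, 5 rose and 1 fell), with Gja1 1.26-fold higher and Glul, the glutamine synthetase, 1.21-fold lower. Among endothelial, mural and fibroblast markers, 2 of 19 measured members rose, 2 fell and 15 did not pass (adjusted over the list alone, 2 rose and 2 fell), with Tek 4.22-fold higher and Dcn 2.64-fold lower. Their camera adjusted p was 0.713, and those of the oligodendrocyte and microglia lists were 0.53 and 0.53. Among the axon guidance genes, 14 of 38 measured members fell, 4 rose and 20 did not pass (adjusted over the list alone, 4 rose and 15 fell) (camera adjusted p = 0.0718), and Sema5a rose 1.83-fold while Efna5 fell 1.99-fold. Of the mitochondrially encoded genes, 3 of 15 measured members rose and 12 did not pass (adjusted over the list alone, 3 rose) (camera adjusted p = 0.0559), with ND2 1.24-fold higher. In the immediate early list, 8 of 30 measured members fell, 4 rose and 18 did not pass (adjusted over the list alone, 4 rose and 8 fell) (camera adjusted p = 0.0615). The chromatin regulator, oxidative phosphorylation, heat shock, unfolded protein and ribosomal protein lists had camera adjusted p of 0.0861, 0.53, 0.2, 0.384 and 0.404. The axon guidance list passed with a block for the number pair (adjusted p = 0.0462), with number pairs summed (0.0295) and within numbers 3 and 4 (0.0295), but not with the replicate number as a block (0.0708). Mitochondrially encoded genes passed within numbers 3 and 4 (0.0257) but not with either block or with pairs summed (0.0544 to 0.0771). Within numbers 1 and 2, where GFP has 1 library, the medians of these lists were -0.093 and 0.13. With an estimated correlation in the fit of all libraries, adjusted p was 0.569 for the axon guidance list, 0.557 for mitochondrially encoded genes and 0.857 for nuclear oxidative phosphorylation genes. Nuclear oxidative phosphorylation genes had a median of 0.070 within numbers 1 and 2 alone, with the same single GFP library. Single libraries decided several of these lists. The camera adjusted p became 0.025 without GFP 3, 0.0441 without GFP 4 and 0.038 without CFT 2 for the axon guidance list, 0.0471 without GFP 3, 0.0441 without GFP 4, 0.0452 without CFT 2, 0.0422 without CFT 4, 0.0433 without WT 2 and 0.0388 without WT 3 for mitochondrially encoded genes. It was 0.0107 without GFP 2 and 0.0479 without CFT 1 for immediate early genes, 0.0298 without GFP 2 for chromatin regulators, 0.0218 without GFP 2 for nuclear oxidative phosphorylation, 0.0378 without GFP 2 for ribosomal proteins. Without CFT 2 the number of lists that passed was 16 in place of 10.

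The rise of low-abundance genes was present here too, with 200 higher and 39 lower among genes under 1 CPM (median 0.29). The CPM values of the groups did not overlap in 6144 genes (35.5%, against 5.71% by chance). Within numbers 1 and 2, where GFP has 1 library, 3240 genes passed, and within numbers 3 and 4 there were 6739. The number of called lists that also passed was 9 of 10 in numbers 1 and 2, without the cell cycle list, and 10 of 10 in numbers 3 and 4. With number pairs summed 2391 genes passed and 24 of the 115 named genes called lost their call, which of the genes named above were H1f10 (adjusted p = 0.0581), Mrap2 (0.109) and St18 (0.102). For Baiap3, Catsperg, Cfap44, Dcn, Efna5, Eqtn, Glul, Gphn, Gria1, H1f2, Hist1h2bq, Lrrtm2, Misp, Mogat2, Nefm, Sema5a and Slc9a2, overlapping genes in the GRCr8 table leave the values uncertain.

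WT H1.4 neurons differed from GFP neurons in far fewer genes, led by lower astrocyte transcripts. By the list test 9 of 26 lists passed, and with an estimated inter-gene correlation the inhibitory neuron, astrocyte and endothelial, mural and fibroblast lists did. Gfap fell 1.76-fold (305 ± 16.6 against 537 ± 41.9 CPM, log2 fold change -0.82, SE 0.069, adjusted p = 5.21e-05). The collagen genes Col3a1 and Col1a2 fell 2.26-fold (6.40 ± 1.37 against 14.5 ± 3.10 CPM) and 2.13-fold (6.43 ± 1.43 against 13.8 ± 2.38 CPM), and the growth factor gene Igf2 fell 2.46-fold (2.40 ± 0.305 against 5.96 ± 0.532 CPM, adjusted p = 0.0014). In all, 163 of 17294 genes passed, 75 higher and 88 lower, and 1 rose and 7 fell at least 2-fold. The rise was in Rgl3, named after its values were seen (0.859 ± 0.179 against 0.192 ± 0.0543 CPM, adjusted p = 0.0494). With number pairs summed only Gfap passed and the other 33 of the 34 named genes called here did not, whereas 248 genes passed with the replicate number as a block and 404 with a block for the number pair. This comparison asks what the wild-type histone itself does when it is added.

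Among the largest rises within the limits of 2 CPM and no overlap, Psd, an exchange factor for the GTPase ARF6, rose 1.48-fold (382 ± 14.2 against 259 ± 15.3 CPM, log2 fold change 0.56, SE 0.072, adjusted p = 0.0014). Tbc1d16 and the tumour suppressor gene Nf2 rose, with log2 fold changes of 0.48 (316 ± 13.0 against 226 ± 16.5 CPM, adjusted p = 0.000108) and 0.49 (264 ± 8.84 against 187 ± 13.0 CPM, adjusted p = 0.000167). Cspg4, the NG2 proteoglycan of oligodendrocyte precursors, rose, with a log2 fold change of 0.58 (SE 0.095, adjusted p = 0.00306), and Pola2, a DNA polymerase subunit gene, rose by 0.58 log2 units, with an adjusted p of 0.0093 that became 0.0747 without GFP 4. Irs4, Kctd13, Arhgap33, Unc5b and Zfp51 completed the 10 largest rises within these limits at log2 fold changes of 0.71, 0.56, 0.51, 0.49 and 0.46 (adjusted p from 0.0199 to 0.0489). The imprinted RNA gene H19 fell 3.02-fold (0.959 ± 0.341 against 2.97 ± 0.433 CPM, adjusted p = 0.00503), and its adjusted p became 0.058 without GFP 4. Trnp, Col1a1, Tlcd1, Gad2 and Gpr37l1 completed the 10 largest falls within these limits at 2.24-fold, 1.90-fold, 1.77-fold, 1.65-fold and 1.63-fold (adjusted p from 0.00497 to 0.0267). The calls of Irs4, Kctd13, Arhgap33, Unc5b, Zfp51, Trnp, Col1a1, Tlcd1, Gad2 and Gpr37l1 were each lost without at least 1 library. The adjusted p became 0.15 without GFP 3, 0.228 without GFP 4, 0.076 without WT 2 and 0.0672 without WT 3 for Irs4. For Kctd13 the adjusted p became 0.207 without GFP 3, 0.266 without GFP 4, 0.113 without WT 1, 0.121 without WT 2, 0.0807 without WT 3 and 0.12 without WT 4. It became 0.185 without GFP 3, 0.18 without GFP 4, 0.0701 without WT 1, 0.0988 without WT 2, 0.0792 without WT 3 and 0.0992 without WT 4 for Arhgap33. For Unc5b the adjusted p became 0.147 without GFP 3, 0.205 without GFP 4, 0.0549 without WT 1, 0.0531 without WT 2 and 0.0694 without WT 4. It became 0.158 without GFP 3, 0.361 without GFP 4, 0.0563 without CFT 1, 0.0533 without CFT 2, 0.0575 without CFT 3, 0.105 without WT 1, 0.121 without WT 2, 0.0623 without WT 3 and 0.134 without WT 4 for Zfp51. For Trnp the adjusted p became 0.0593 without GFP 2, 0.0511 without GFP 3, 0.17 without GFP 4, 0.0889 without WT 1, 0.0724 without WT 2, 0.075 without WT 3 and 0.0726 without WT 4. It became 0.122 without GFP 3, 0.0937 without WT 2, 0.0827 without WT 3 and 0.0608 without WT 4 for Col1a1. For Tlcd1 the adjusted p became 0.0553 without GFP 4. It became 0.119 without GFP 3, 0.166 without GFP 4, 0.0609 without WT 2 and 0.0664 without WT 4 for Gad2. For Gpr37l1 the adjusted p became 0.086 without GFP 3, 0.18 without GFP 4 and 0.0531 without WT 2.

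The astrocyte list had the smallest adjusted p. Of its markers, 7 of 17 measured members fell and 10 did not pass (adjusted over the list alone, 12 fell) (median log2 fold change -0.24, camera adjusted p = 2.98e-25, adjusted p = 7.55e-05 with an estimated correlation). Mlc1, Glul and Fabp7 fell, with log2 fold changes of -0.40, -0.36 and -0.32. For endothelial, mural and fibroblast markers, 4 of 19 measured members fell and 15 did not pass (adjusted over the list alone, 1 rose and 6 fell) (median log2 fold change -0.14, camera adjusted p = 3.34e-07, adjusted p = 0.0272 with an estimated correlation). Besides the collagens, the smooth muscle gene Tagln fell 1.54-fold (adjusted p = 0.0101, but 0.0606 without GFP 3 and 0.141 without GFP 4). Inhibitory neuron genes were lower, 7 of 25 measured members fell and 18 did not pass (adjusted over the list alone, 10 fell) (median log2 fold change -0.14, camera adjusted p = 8.40e-08, adjusted p = 0.0214 with an estimated correlation). Slc32a1, the vesicular GABA transporter, and Gad2, which makes GABA, fell 1.38-fold and 1.65-fold. The adjusted p of Slc32a1 rose from 0.00592 to 0.103 without GFP 4. Vgf fell (63.4 ± 3.72 against 88.6 ± 8.28 CPM, log2 fold change -0.48, SE 0.067, adjusted p = 0.00115), while its neuropeptide list had a camera adjusted p of 0.192, and 1 of 18 measured members fell and 17 did not pass (adjusted over the list alone, 2 fell).

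The other 6 lists passed with few or no single genes past the threshold. Nuclear oxidative phosphorylation genes were lower, 1 of 35 measured members fell and 34 did not pass (adjusted over the list alone, 4 fell) (median log2 fold change -0.091, camera adjusted p = 2.41e-07, adjusted p = 0.463 with an estimated correlation). The median of that list was 0.053 within numbers 1 and 2, where GFP has 1 library, and -0.16 within numbers 3 and 4, where it passed as lower. Glycolysis and hypoxia genes were higher as a list, 0 of 23 measured members passed (adjusted over the list alone, 0 passed) (median log2 fold change 0.27, camera adjusted p = 1.34e-09, adjusted p = 0.463 with an estimated correlation), and Gapdh and P4ha1 had log2 fold changes of 0.27 (SE 0.12, adjusted p = 0.407) and 0.62 (SE 0.30, adjusted p = 0.483). Ankrd37 stood at 3.08 ± 0.777 against 1.28 ± 1.04 CPM (SE of the log2 fold change 0.47, adjusted p = 0.304). Ankrd37 passed without GFP 2 (adjusted p = 0.0288). Axon guidance genes were higher, 2 of 38 measured members rose and 36 did not pass (adjusted over the list alone, 6 rose and 2 fell) (median log2 fold change 0.079, camera adjusted p = 0.000744, adjusted p = 0.463 with an estimated correlation). Chromatin regulators were higher as a list, 0 of 39 measured members passed (adjusted over the list alone, 0 passed) (median log2 fold change 0.050, camera adjusted p = 0.00191, adjusted p = 0.344 with an estimated correlation), with a camera adjusted p of 0.0522 without GFP 3. Their members Kdm6b, Ehmt1 and Chd3 had log2 fold changes of 0.26 (SE 0.084, adjusted p = 0.202), 0.10 (SE 0.041, adjusted p = 0.332) and 0.11 (SE 0.046, adjusted p = 0.379), and Kdm6b passed without GFP 2 (adjusted p = 0.0043). Immediate early genes were lower, 1 of 30 measured members fell and 29 did not pass (adjusted over the list alone, 1 rose and 1 fell) (median log2 fold change -0.11, camera adjusted p = 0.0182, adjusted p = 0.463 with an estimated correlation), and the camera adjusted p became 0.0707 without GFP 3, 0.0826 without GFP 4 and 0.0686 without WT 2. Interferon-response genes were lower as a list, 0 of 20 measured members passed (adjusted over the list alone, 0 passed) (median log2 fold change -0.15, camera adjusted p = 0.0437, adjusted p = 0.593 with an estimated correlation), and the camera adjusted p became 0.124 without GFP 2, 0.07 without WT 1 and 0.152 without WT 3. The interferon list also lost its call with the replicate number as a block. B2m, Ddx58 and Bst2 of that list had log2 fold changes of -0.20 (SE 0.062, adjusted p = 0.158), -0.38 (SE 0.18, adjusted p = 0.436) and -0.88 (SE 0.50, adjusted p = 0.538).

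Most neuronal lists that were lower in H1.4 CFT did not pass in WT H1.4 when all libraries were used. Camera adjusted p was 0.352 for excitatory postsynaptic genes, 0.195 for presynaptic genes, 0.975 for channels, 0.938 for mature neuron genes and 0.0673 for immature neuron genes, of which Sox11 rose 1.22-fold (adjusted p = 0.00802, but 0.0574 without GFP 3 and 0.122 without GFP 4). It was 0.938 for cholesterol synthesis, 0.352 for core histones, 0.231 for the cell cycle, 0.366 for mitochondrially encoded genes and 0.938 for ribosomal proteins. Some of these passed when a library was left out, immature neuron genes at 0.0479 without GFP 3 and 0.0402 without WT 1, the cell cycle at 0.0132 without GFP 2 and mitochondrially encoded genes at 0.0278 without WT 2. The p53, unfolded protein, heat shock, oligodendrocyte, microglia and ependymal lists gave 0.699, 0.352, 0.235, 0.352, 0.975 and 0.391. In the excitatory list the median log2 fold change was -0.0074 and the mean 0.014, and in the oligodendrocyte list they were -0.010 and 0.081, with both tests pointing up. Signs also differed between median, mean and test for the neurofilament, microglia, p53 and ribosomal protein lists, none of which passed.

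The number of genes that passed between WT H1.4 and GFP rested on single libraries. It was 306 without GFP 2, 44 without GFP 3 and 45 without GFP 4, and 105, 91, 103 and 84 without WT 1, 2, 3 and 4. Within numbers 1 and 2, where GFP has 1 library, 216 genes passed, and within numbers 3 and 4 there were 1608. Of the 9 lists called, 5 kept their call and direction within numbers 1 and 2, where the immediate early, axon guidance, chromatin regulator and oxidative phosphorylation lists did not. Within numbers 3 and 4 it was 7, without the immediate early and interferon lists. Another 7 lists passed within numbers 1 and 2. As GFP has 1 library there, only the medians of these lists are given. They were -0.036 for excitatory postsynaptic genes, -0.065 for presynaptic genes, -0.062 for channels and 0.068 for immature neuron genes. For cholesterol synthesis the median was -0.023, and for the ribosomal protein and mitochondrially encoded lists 0.10 and 0.064. Another 4 passed within numbers 3 and 4. These were excitatory postsynaptic genes (median 0.049, adjusted p = 0.000683), the cell cycle (-0.091, 0.0329), and the ribosomal protein and mitochondrially encoded lists with the opposite sign (medians -0.073 and -0.16). Immature neuron genes also passed with a block for the number pair (0.0438), but not with number pairs summed. Non-overlapping CPM values were found in 2114 genes (12.2%, against 5.71% by chance). For Ankrd37, Arhgap33, Chd3, Col1a1, Cspg4, Glul, H19, H1f2, Igf2, Mlc1 and P4ha1, overlapping genes in the GRCr8 table again leave the values uncertain.

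**Figure D5:**
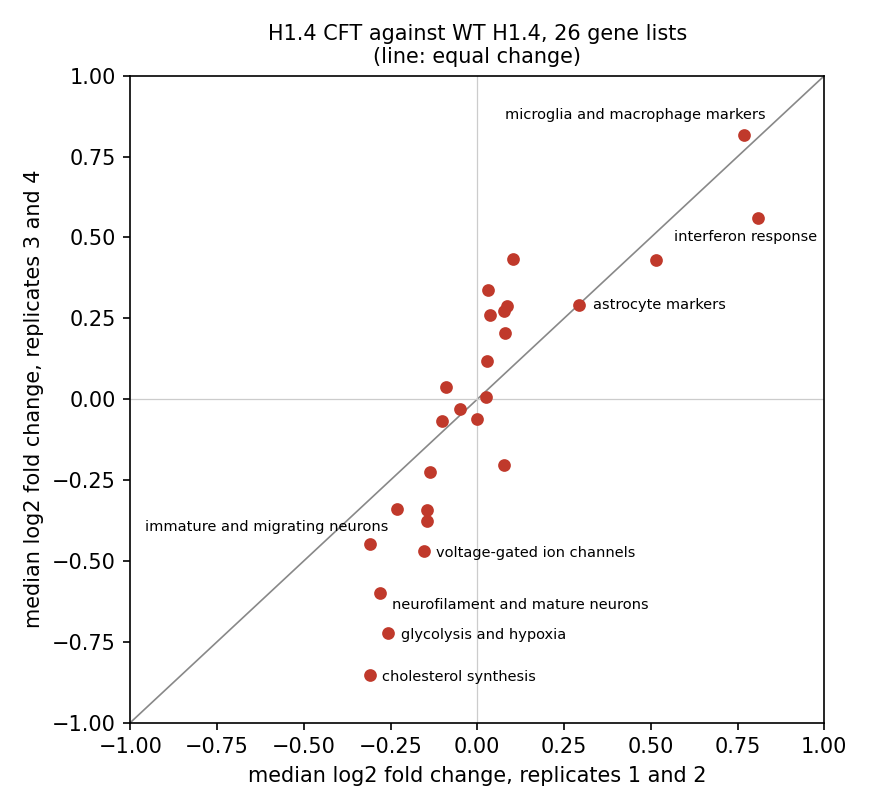
Median log2 fold change of each list within numbers 3 and 4 against that within numbers 1 and 2, for H1.4 CFT against WT H1.4, with 1 point per list and the line of equal change. Cholesterol synthesis genes had a median of -0.31 within numbers 1 and 2 and -0.85 within numbers 3 and 4.

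The genes called for H1.4 CFT and for WT H1.4 against GFP overlapped in part. Of the 163 genes that passed for WT H1.4, 67 passed in the same direction for H1.4 CFT, 14 passed in the opposite direction and 82 did not pass. H1f2, H1f0, Egr3 and Vgf fell in both, and Gfap, Col3a1 and Col1a2 were not among the 67. These genes were 30 higher and 37 lower in both, where independent lists of the same sizes would share 9.98 and 14.2. All 11 libraries, GFP included, were also simulated with no group effects and no number pairs. There both comparisons with the simulated GFP libraries shared 0.2 genes on average over 20 simulations, and at most 1. The simulated number leaves out the effects and the number for independent lists leaves out the shared controls, so the excess over either does not measure a shared effect. Both comparisons use the same 3 GFP libraries, which are too few to split, and part of the excess can come from them. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.291 and a Spearman correlation of 0.255, where simulated unchanged groups gave 0.602 and 0.542. Effects that are not shared lower a correlation, so these lower values do not speak against a shared effect. The covariance of the log2 fold changes was 0.0339, against a mean of 0.0267 (0.0253 to 0.0293) in the simulations. That excess does not measure a shared effect either, since the simulations hold no number pairs. The overlap was 0 with number pairs summed and 170 with a block for the number pair, and 0 with a fold threshold of 0.25 on the log2 scale. It moved with single libraries, to 144 without GFP 2, 16 without GFP 3 or GFP 4, and 41, 37, 34 and 31 without WT 1, 2, 3 and 4.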

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

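The tests on depth, on the receptor genes, on the reads behind the folds of numbers 1 and 2, on single lists of other cell types and on uneven number pairs were chosen after the results were seen. Of 402 groups of 4 libraries, 10 (2.49%) had a library far from the others by Dixon's ratio of the gap to the range at its 95% critical value, which chance exceeds in about 5% of groups.

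In WT H1.4, Aurkb stood at 12.5 CPM in WT 3 against 10.5 to 10.6 in the others (ratio 0.967). Ccdc153 stood at 2.85 CPM in WT 4 against 3.69 to 3.85 (0.842), and H1f0 at 76.4 CPM in WT 2 against 83.4 to 84.0 (0.918). Hist3h2a was at 42.6 CPM in WT 1 against 39.8 to 40.1 (0.886), and Mcm2 at 28.2 CPM in WT 4 against 26.2 to 26.4 (0.874). Uqcrc2 was at 155 CPM in WT 2 against 144 to 145 (0.874), and Vgf at 68.9 CPM in WT 4 against 60.9 to 62.2 (0.832). In H1.4 CFT, Atp5pb was at 182 CPM in CFT 3 against 173 to 174 (0.849) and Tek at 4.61 CPM in CFT 4 against 3.01 to 3.26 (0.840). Genes detected without thinning numbered 23807 in CFT 4 against 23535 to 23552 (0.938).

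The effect of the group differed between the number pairs in a test of the interaction. It passed for 1760 genes in H1.4 CFT against WT H1.4, 723 in H1.4 CFT against GFP and 255 in WT H1.4 against GFP. Of the 1760 genes, 1267 had a larger change of equal direction in numbers 3 and 4, 40 in numbers 1 and 2, and 453 had opposite directions. The corresponding counts were 552, 13 and 158 of the 723, and 44, 1 and 210 of the 255. Over the 6217 genes called in all libraries the median fold size was 0.28 in numbers 1 and 2 and 0.43 in numbers 3 and 4 on the log2 scale.

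The first pattern weighed was this larger response to H1.4 CFT in numbers 3 and 4. A culture difference shared by all groups would cancel in the interaction, and the 1760 genes (10.2% of those tested) argue against it as the whole cause. Fewer reads behind numbers 1 and 2 are argued against as well, since after thinning 1403 genes still passed and 97.7% of the 1053 with equal direction had the larger fold in numbers 3 and 4. The planned slope of the folds in numbers 3 and 4 on those in 1 and 2 was 0.883 after thinning and 0.966 before, but choosing genes called in numbers 1 and 2 draws a slope under 1, so it could not decide on depth. A larger share of astrocytes stays open (median interaction of their markers -0.061, 95% bootstrap interval -0.21 to 0.13), as does an unlabelled difference in how the pairs were made, which may differ between groups. The interaction test takes its spread from libraries of the same group and pair. A difference between the pairs of a single group would also pass it, so it does not show that the response itself differed.

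The second pattern was the rise of low-abundance genes in H1.4 CFT. Depth is argued against, since 1069 more genes were detected than in WT H1.4 after thinning, above the spread between libraries. Summed olfactory and vomeronasal receptor genes, taken as silent, had a log2 ratio of -0.028 (SE 0.10) against GFP, so no extra reads over them were seen there. The median in genes under 1 CPM was 0.29. Against WT H1.4 the ratio was 0.25 (SE 0.11), beside 0.34. The receptor sum used no low-count filter, whereas the genes under 1 CPM had passed it, some perhaps through high H1.4 CFT values. Such unlike sets cannot decide on reads from DNA or unspliced RNA over silent genes, which stay open in both comparisons. Another cell type added to the cultures stays open. The 54 markers of 4 other cell types had a median against GFP of 0.043 (95% bootstrap interval -0.071 to 0.095), but a pooled median cannot speak against a single type. Taken alone, the medians were 0.067 for astrocyte (interval -0.10 to 0.14), 0.11 for oligodendrocyte (-0.084 to 0.35), 0.22 for microglia (-0.50 to 1.75), -0.076 for endothelial, mural and fibroblast (-0.28 to 0.060) and 0.30 for ependymal and choroid plexus markers (-0.083 to 0.54). A loss of repression by the mutant histone may remain as a hypothesis, which these data do not test.

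The third pattern was the lower astrocyte markers in WT H1.4 than in GFP. Fewer astrocytes would lower all markers alike only if no other cells in the cultures expressed them, which was not tested. Of the 17 markers, 47.1% (8) lay within 2 SE of the list's median, and Cochran's Q was 150.1 on 16 degrees of freedom. The falls were thus unequal, but this cannot decide on fewer astrocytes. Uneven number pairs are argued against by the pair with replicate GFP libraries taken alone. There the list was lower (median -0.21, camera adjusted p = 2.75e-26). This p takes its spread from libraries of the same group and pair, so it does not cover differences between cultures. The other pair gave a median of -0.29. GFP 2 is its only GFP library, so its test is not used. Fewer astrocytes and a change within astrocytes may remain, as may a difference between cultures that no label records.

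Other splits of the libraries were counted for each comparison. The count of genes was reached by 1 of 35 splits, the real one, in each. These 35 splits take no account of the number pairs. Among the 8 that part as many equal replicate numbers as the real one, the real one was the highest in each comparison. As 8 are too few for a share under 0.05, the splits alone cannot exclude chance in any comparison. H1.4 CFT against WT H1.4 gave 6217 genes and the highest other split 0. H1.4 CFT against GFP gave 5098 and the highest other split 2710, which sets CFT 1 with the 3 GFP libraries and so keeps most of the real grouping. WT H1.4 against GFP gave 163 and the highest other split 24, which sets numbers 3 and 4 against the rest and so follows the number pairs. With number pairs summed 1 gene passed in that comparison, against 2723 and 2391 in those of H1.4 CFT, so chance is not excluded for the 163 genes once the pairs are counted.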

How the results depend on the processing

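The alternatives for the number pairs (a block, summed counts and tests within a pair) were chosen after the data were seen, and the others before. RLE scaling, the stricter filter, limma-voom and the non-robust spread kept every count of genes and lists within 1.5 times its value. Gene counts under these 4 ran from 5505 to 6366 for H1.4 CFT against WT H1.4, 4593 to 5102 for H1.4 CFT against GFP and 134 to 162 for WT H1.4 against GFP. The median of all genes stayed within 0.05 of 0 on the log2 scale in every setting tabulated for the 3 comparisons.

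A fold threshold of 0.25 asks for larger changes and gave 1835, 1502 and 5 genes in the 3 comparisons, in the order above, and an overlap of the 2 comparisons with GFP of 0 genes. With an estimated inter-gene correlation 2, 0 and 3 lists passed. Fry, which does not compare a list with other genes, gave 16 lists for H1.4 CFT against GFP and 3 for WT H1.4 against GFP. With number pairs summed, which leaves fewer samples, 2723, 2391 and 1 genes passed and the overlap was 0. Without a low-count filter 18 lists passed for H1.4 CFT against GFP, 462 genes for WT H1.4 against GFP, and the overlap was 162. For WT H1.4 against GFP, DESeq2 gave 248 genes, the replicate block 248, only the 2 groups compared 348 and the number-pair block 404. The overlap was 103 with the replicate block, 1.2e+02 (rounded) with only the 2 groups and 170 with the number-pair block. Within numbers 1 and 2, which hold fewer libraries, H1.4 CFT against GFP gave 3240 genes. Within numbers 3 and 4, WT H1.4 against GFP gave 1608 genes and the overlap was 537. Where no cause is named, the cause was not tested.

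Leaving out each library gave 5030 (without CFT 3) to 6444 (without GFP 2) genes for H1.4 CFT against WT H1.4 and 3966 (without GFP 4) to 5132 (without CFT 2) for H1.4 CFT against GFP. Lists in the latter ranged from 9 without CFT 3 to 16 without CFT 2. WT H1.4 against GFP ranged from 44 genes without GFP 3 to 306 without GFP 2, and was 45 without GFP 4 and 105, 91, 103 and 84 without WT 1 to 4. The overlap ranged from 16 without GFP 3 or GFP 4 to 144 without GFP 2, and was 41, 37, 34 and 31 without WT 1 to 4. Of the named genes that passed, 116 of 121, 106 of 115 and 12 of 34 passed without each library in turn, in the order of comparisons above, and 0 turned. Where an omission leaves few libraries, their spread is assumed to be that of the other groups.

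The direction of a list's test can differ in sign from its median. Among lists that passed in the main fit or in the alternative, the direction was reversed in 7 cases. All were within number pairs, and the cause was not tested. In numbers 1 and 2 GFP has 1 library, so medians alone are given there. For H1.4 CFT against GFP this was nuclear oxidative phosphorylation within numbers 1 and 2 (median 0.070). For WT H1.4 against GFP within numbers 1 and 2 it was excitatory postsynaptic genes (-0.036), axon guidance (0.0028) and cholesterol synthesis (-0.023). Nuclear oxidative phosphorylation (0.053) and mitochondrially encoded genes (0.064) were reversed there too. Within numbers 3 and 4 it was ribosomal protein genes (median -0.073, adjusted p = 2.66e-07). With the replicate block, for WT H1.4 against GFP, interferon-response genes had an adjusted p of 0.0639 and Zfp51 of 0.0554. A list that turned but passed in neither fit is counted here as the same. Over all settings, single lists and named genes were the same in 580 and 2809 cases for H1.4 CFT against WT H1.4, lost the call in 26 and 79, and gained one in 13 and 0. The counts were 533 and 2651, 15 and 99, and 71 and 0 for H1.4 CFT against GFP, and 574 and 837, 24 and 176, and 15 and 16 for WT H1.4 against GFP.

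The mean level of H1f4 in H1.4 CFT was 0.346 CPM and ran from 0.311 without CFT 2 to 0.366 without CFT 3 over the settings that gave a value. DESeq2, limma-voom, the replicate block, the fit of only 2 groups and the non-robust spread do not change this level, so they gave no value of their own. Of the smallest simulated changes, 48% to 50% were recovered, and whether depth, spread or the number of libraries limits this was not tested.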

Other observations

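Both hypotheses below took up patterns seen in these same data. Their tests were written before the tests were run, whereas the choice of the gene families was made after their values were seen. Families were groups of at least 10 tested genes with a shared symbol stem, 167 in each comparison, tested with camera as the lists were.

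Single cilium and sperm genes (Cfap44, Acr, Eqtn and Catsperg) stood among the largest rises in H1.4 CFT, though Cfap57 of the Cfap family was among the 10 largest falls against GFP (log2 fold change -1.70). The spans of Cfap44, Acr, Eqtn and Catsperg overlap another gene, so their values are uncertain. Sperm genes were not tested as a set. Gene families of the motile cilium might still rise together. Of the 4 tests of the Cfap and Dnah families against WT H1.4 and GFP, 0 passed (adjusted p = 0.145 and 0.154 against WT H1.4, 0.325 and 0.168 against GFP). All 4 pointed up, with medians of 0.32 and 0.25 against WT H1.4 and 0.22 and 0.34 against GFP. In the Cfap family (30 genes) 11 and 12 genes were higher and 4 lower in each, and in the Dnah family (13) 5 and 4 were higher and 0 lower. The bound set in advance, at most 1 passing test, was wrong as a sign of no rise, since missing a threshold over 167 families does not show that the families did not rise, so the question stays open.

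Genes held low in the GFP libraries might rise most in H1.4 CFT. The Spearman correlation across genes, which are not independent replicates, between the level in GFP 2 and the fold against GFP 3 and 4 was -0.25 for H1.4 CFT (-0.27 to -0.19 by library). It was 0.054 for WT H1.4, just outside the bound of 0.05 set in advance, so the test does not decide.

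Against WT H1.4, the Col (39 genes), Hist (10), Pcdhb (18) and Taf (22) families were higher in H1.4 CFT (adjusted p = 0.00225, 0.0290, 0.0291 and 0.0332), and the Cacna family (13) was lower (0.0398). Against GFP, the Pcdhb family was higher (0.0440). In WT H1.4 against GFP, the Aldh and Col families were lower (0.0151 and 0.0229) and the Tbc and Zfp families higher (0.0229 and 0.0470). With an estimated correlation 0 of these passed (adjusted p from 0.546 to 0.988). Members of the Pcdhb and Hist families are close paralogs, so their values are uncertain. Only polyadenylated transcripts of the Hist family were counted.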
